A study of Bos taurus with 29 samples.

How the data were processed

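The data are messenger RNA libraries of single cattle oocytes. Per the labels' protocols, cumulus-oocyte complexes were aspirated from follicles of FSH-treated donors under ultrasound guidance. GV oocytes were denuded at collection, IVM oocytes after 22 h in medium with EGF and FSH, and CNP_IVM oocytes after 6 h with 200 nM CNP in medium without EGF followed by 22 h of maturation (28 h in all). Metaphase II was judged by the polar body. Libraries were made from oocytes frozen singly with SMART-Seq v4, which primes on poly(A), and Nextera XT, and read as pairs on a HiSeq X. The submitters' processing notes name Trim Galore 0.6.7, FastQC, HISAT2 2.2.1, featureCounts 2.0.1 and edgeR, with no order or role. They also name the mouse build GRCm39, while the table's gene names are cattle symbols: 13356 of its 13502 names are current symbols in the RefSeq table of cattle assembly ARS-UCD2.0, 41 are older symbols and 105 had no match. Of the names, 628 are LOC numbers, and no coordinates are given here.

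The authors deposited 1 table of normalised values, named for TPM. The deposited values are CPM, not TPM: within each library every value is a whole multiple of a single step, the same for all genes, so gene length does not enter. With a tolerance of 0.01 read, 100% of the values gave whole reads. Recovered library totals were 20159662 to 39340040 reads, of which 97.1 to 97.6% lay in the listed genes. Of 29 labelled samples, 22 had a column in the table (7 of 9 GV, 8 of 10 IVM and 7 of 10 CNP_IVM), and 7 were not analysed here. Columns were matched by the column name in each sample's description, and groups were taken from the titles. No column of values was left over. GV replicate 9 has a GV title and a treatment label of in vitro maturation, and was grouped by title. No 2 libraries of a group were copies of each other: the smallest chi-square per degree of freedom between recovered reads of a pair was 38.0, over genes with at least 20 reads in the pair.

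The design written before the data were examined took each oocyte as a replicate, assumed TPM and planned limma-trend tests, camera tests of gene lists and exact permutation tests. Those tests were run first and then set aside, and none of their results is given. The labels name no donor or culture for any oocyte, so oocytes of a group may share an animal, and each group was counted as 1 sample. The results are therefore descriptions without p-values. Ranges and SDs show the spread between the oocytes measured, which is not the spread between animals.

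Genes with at least 1 CPM in at least 6 libraries were kept (11852). The log2 difference of a gene is that of its group means, each with a pseudocount of 1 CPM, which understates differences of low genes. Genes were counted as at least 2-fold higher or lower on that scale. These counts, which replace the planned numbers of called genes, were chosen after the data had been examined. For each of 25 gene lists written before the data were examined, the text gives its members past each side of 2-fold, its median and the percentile of that median among 10000 random lists with as many genes in each of 20 bins of mean expression. Percentiles under other settings used 2000 random lists. The lists cover oocyte factors, the meiotic cell cycle, spindle and kinetochore, cyclic nucleotide signalling, messenger RNA storage and decay, ribosomal proteins, translation factors, mitochondrial ribosomal proteins, nuclear respiratory genes, the mitochondrial genome, mitochondrial dynamics, glycolysis and the citric acid cycle, lipid metabolism, redox, stress and unfolded proteins, the proteasome, apoptosis, DNA repair, chromatin, histones, cytoskeleton and transport, EGF and TGF-beta signalling, cumulus and granulosa markers, blood and immune markers, and embryonic genome activation.

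Named genes came from a rule. Per comparison it took the 10 highest and 10 lowest log2 differences among genes with a symbol and a mean of at least 10 CPM in either group, and, among the same genes, per list up to 4 members at least 2-fold apart with the largest differences (2 per direction where both occur). NPPC, NPR2, PDE3A, PDE5A, GPR3, GDF9, BMP15, CCNB1, MOS, BTG4, ZP3 and HSD3B1 were taken whatever their values. The written rule also asked for an adjusted p-value and ranked list members by it. Both were replaced by size after the data had been examined. Of the genes the rule took, those given in the text were picked for known function and for values that did not rest on 1 oocyte, after their values had been seen. Recovered reads were also summed per group, with exact 95% Poisson intervals.

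Steps were tested on simulated reads drawn for the 11852 genes from each gene's mean over all libraries, its spread within groups and the real library totals, with 100 genes per comparison given each of 2 sizes of change. Of genes made 4-fold different (log2 2), 92% in IVM against GV, 95% in CNP_IVM against GV and 91% in CNP_IVM against IVM came out at least 2-fold apart, all in the right direction. Of genes made exactly 2-fold different (log2 1), 36% did in each comparison, with 97 to 98% in the right direction. Of unchanged genes, 1.60%, 1.72% and 1.52% did. All 10 simulated lists shifted by log2 0.5 lay outside the central 95% of random lists in each comparison, and 0 of the 10 unshifted ones did. In these draws genes varied independently, lists were random and the list shift was added to the computed differences. No shift of all genes was simulated. These rates need not hold for the real lists, whose members may vary together, or for the real libraries. Alternatives tried were pseudocounts of 0.1 and 5 CPM, other filters, quantile normalization, trimmed-mean (TMM-like) factors with 30% of ratios and 5% of levels trimmed per side, rescaling without mitochondrial-genome and ribosomal protein genes, leaving out each library, the mean of log2 values and summed reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.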

Results

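Messenger RNA of single cattle oocytes was measured at 2 stages of meiosis. Germinal vesicle (GV) oocytes, which are arrested before meiosis resumes, were stripped of their cumulus cells at collection. Metaphase II (MII) oocytes came from 2 culture systems. In conventional in vitro maturation (IVM) the cumulus-oocyte complexes were cultured for 22 h. In the other system (CNP_IVM) they first spent 6 h with 200 nM C-type natriuretic peptide (CNP), a follicular peptide that holds oocytes in meiotic arrest through cyclic GMP, and then 22 h in maturation medium. The table held 7 GV, 8 IVM and 7 CNP_IVM oocytes, and 7 further labelled samples were not analysed here. Library totals lay between 20159662 and 39340040 reads. Values are read counts scaled to the library total (CPM), and ranges in parentheses run from the lowest to the highest oocyte of the group. A level is thus a share of a library primed on poly(A). Changes in the amount of a transcript, in its poly(A) tail and in the rest of the library were not told apart in any comparison.

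Each library was 1 oocyte and the labels name no donor animal, so each group counted as 1 sample and tests that took oocytes as replicates were set aside and none is given. All differences below describe these oocytes. A further pair of limits holds throughout. Every CNP_IVM oocyte was cultured for 28 h in all against 22 h for IVM, with no 6 h culture without CNP, so CNP and time in culture were confounded. GV replicate 9 carried a GV title but a treatment label of in vitro maturation, was grouped by its title, and had 9381 genes at 1 CPM or more, where the other 6 GV oocytes had 11311 to 11798.

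The number of genes at 1 CPM or more averaged 11320.0 ± 869 (SD, n = 7) in GV oocytes, 10216 ± 564 (SD, n = 8) after IVM and 9653 ± 151 (SD, n = 7) after CNP_IVM. Summed transcripts of the oocyte factor list made up 44629 ± 3059 CPM (41523 to 49369) in GV, 63788 ± 4451 CPM (58018 to 68292) in IVM and 68566 ± 6309.7 CPM (63211 to 78605) in CNP_IVM oocytes. Summed cumulus and granulosa cell markers were 1027 ± 246 CPM (802 to 1515) in GV, 594 ± 126 CPM (431 to 768) in IVM and 329 ± 28.4 CPM (281 to 373) in CNP_IVM oocytes, so every CNP_IVM oocyte lay below every IVM oocyte. Summed blood and immune cell markers were 287 ± 58.8 CPM (209 to 386), 36.9 ± 15.2 CPM (20.03 to 58.5) and 25.1 ± 9.69 CPM (11.5 to 39.5) in the same order. The values after ± are SDs between oocytes. STAR alone averaged 316 CPM in IVM and 93.9 CPM in CNP_IVM oocytes, so 1 gene carried much of the difference in the cumulus and granulosa sum. Of 19 such markers past the filter, 0 were at least 2-fold higher, 4 at least 2-fold lower and 15 under 2-fold in CNP_IVM against IVM. VWF alone averaged 225 CPM of the blood and immune sum in GV oocytes.

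The first comparison describes conventional maturation, IVM against GV. The medians of the translation, respiration and antioxidant lists were lower after IVM, and those of the DNA repair, chromatin and messenger RNA decay lists were higher, with members on both sides and many under 2-fold. GPX4, an enzyme that reduces lipid hydroperoxides, averaged 14.5 CPM (8.34 to 30.4) after IVM against 982 CPM (306 to 1380.5) in GV oocytes, a log2 difference of -5.99. NDUFA8, a subunit of respiratory complex I, was at 20.01 CPM (9.88 to 33.2) against 922 CPM (613 to 1095), and POLR2G, a subunit of RNA polymerase II, at 15.96 CPM (10.1 to 25.8) against 765 CPM (297 to 1028). In the other direction, the RNA helicase gene DDX3X was at 1079 CPM (682 to 1544) against 113 CPM (76.9 to 160.4), a log2 difference of 3.25. DBT, a subunit of branched-chain keto acid dehydrogenase, was at 229 CPM (157 to 292) against 24.9 CPM (18.8 to 33.9), and the scaffold protein gene IQGAP1 at 799 CPM (453 to 1058) against 115 CPM (57.9 to 169). For each of these 6 genes every IVM oocyte lay on one side of every GV oocyte.

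Of 81 cytosolic ribosomal protein genes, 1 was at least 2-fold higher, 66 at least 2-fold lower and 14 under 2-fold, with a median log2 difference of -2.02. RPL18 was at 31.8 CPM (22.6 to 46.7) after IVM against 757 CPM (447 to 976) in GV, and RPL38 at 5.39 CPM (2.47 to 10.5) against 114 CPM (78.98 to 144). Their summed level was 7133 ± 915 CPM (5276 to 8131) against 24056 ± 3023 CPM (20507 to 28664). Of 76 mitochondrial ribosomal protein genes, 0 were at least 2-fold higher, 54 at least 2-fold lower and 22 under 2-fold, with a median of -2.04, and examples were MRPL36 (4.65 CPM against 196 CPM) and MRPL27 (6.61 CPM against 232 CPM). Of 82 nuclear genes of the respiratory chain and ATP synthase, 1 was at least 2-fold higher, 59 at least 2-fold lower and 22 under 2-fold, with a median of -2.18. NDUFS7 was at 8.85 CPM (3.64 to 19.8) against 267 CPM (188 to 327), while ATP5PB was the member at least 2-fold higher (293 CPM (159 to 374) against 139 CPM (108 to 201)). Of 63 translation initiation and elongation factor genes, 8 were at least 2-fold higher, 25 at least 2-fold lower and 30 under 2-fold. EIF3G, of the initiation complex eIF3, was at 8.02 CPM (3.88 to 13.7) against 231 CPM (159 to 284), and EIF4G2 was at 407 CPM (262 to 534) against 125 CPM (115 to 142). Ribosomal protein genes have near-identical copies that may share reads, which could not be checked here, so single values of that family are uncertain.

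Among 46 genes of glycolysis, the pentose phosphate pathway and the citric acid cycle, 9 were at least 2-fold higher, 23 at least 2-fold lower and 14 under 2-fold. The citric acid cycle enzyme gene MDH2 was at 26.9 CPM (12.2 to 39.7) against 459 CPM (354 to 546), and the lactate and pyruvate transporter gene SLC16A1 at 149 CPM (112 to 169) against 46.9 CPM (28.1 to 57.7). Among 50 proteasome and ubiquitin genes, 5 were at least 2-fold higher, 24 at least 2-fold lower and 21 under 2-fold, with PSMB5 at 29.1 CPM against 359.8 CPM and PSMD1 at 778 CPM against 276 CPM. Among 46 antioxidant and glutathione genes, 7 were at least 2-fold higher, 19 at least 2-fold lower and 20 under 2-fold. The peroxiredoxin gene PRDX5 was at 31.6 CPM (17.6 to 44.1) against 476 CPM (373 to 586), and catalase, CAT, at 367 CPM (340.0 to 422) against 103 CPM (77.8 to 125). Among 35 histone genes and histone messenger binding factors, 2 were at least 2-fold higher, 25 at least 2-fold lower and 8 under 2-fold. H2AC6 was at 2.11 CPM (1.07 to 3.50) against 67.5 CPM (7.52 to 108), and SLBP, which binds histone messenger RNA, at 714 CPM (486 to 1135) against 289 CPM (175 to 426). Histone genes are near-identical copies and their single values are uncertain.

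The medians of these 8 lists lay below the 2.5th percentile of 10000 random lists matched on expression, as a description of these libraries. Ribosomal, mitochondrial ribosomal, nuclear respiratory and histone lists lay below all of the random lists. The percentile was 0.010 for the proteasome, 0.21 for glycolysis, 0.22 for translation factors and 0.60 for the antioxidant list, whose median log2 difference of -0.83 was -0.52 without GV replicate 9, at percentile 4.05.

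Genes of DNA repair were among those higher after IVM: of 49, 24 were at least 2-fold higher, 6 at least 2-fold lower and 19 under 2-fold, with a median log2 difference of 0.98. LIG4, the ligase of end joining, was at 53.4 CPM (28.8 to 77.7) against 7.22 CPM (2.18 to 10.05), and the recombination gene RAD51C at 275 CPM (210.0 to 333) against 67.9 CPM (51.9 to 103). Of 59 genes of DNA methylation and histone modification, 15 were at least 2-fold higher, 9 at least 2-fold lower and 35 under 2-fold, with a median of 0.69. The histone demethylase gene KDM1B was at 129 CPM (74.4 to 193) against 28.4 CPM (23.1 to 39.6), the deacetylase gene HDAC1 at 94.2 CPM (77.5 to 115) against 22.8 CPM (0.2997 to 36.7), and the arginine methyltransferase gene PRMT7 at 9.46 CPM (3.72 to 18.1) against 65.6 CPM (38.3 to 85.2). Of 67 genes of messenger RNA storage, polyadenylation and decay, 23 were at least 2-fold higher, 7 at least 2-fold lower and 37 under 2-fold, with a median of 0.60. The exonuclease gene XRN1 was at 125 CPM against 33.3 CPM, the RNA-binding protein gene PUM2 at 45.04 CPM against 12.2 CPM, and ZAR1, a maternal factor of stored messenger RNA, at 135 CPM (37.4 to 261) against 1245 CPM (887 to 2062). DNA repair and chromatin lists lay above all 10000 random lists, and the decay list at percentile 99.7.

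The spindle and cell cycle lists went both ways. Of 42 spindle, kinetochore and cohesin genes, 17 were at least 2-fold higher, 8 at least 2-fold lower and 17 under 2-fold. The kinesin gene KIF20A was at 424 CPM (256 to 692) against 93.4 CPM (45.7 to 118), the cohesin gene SMC3 at 893 CPM (680.1 to 1138) against 203 CPM (30.2 to 281), and TUBB4B, a beta-tubulin with close paralogs, at 17.6 CPM (4.70 to 35.5) against 375 CPM (237 to 707). Of 51 genes of the meiotic cell cycle, 13 were at least 2-fold higher, 7 at least 2-fold lower and 31 under 2-fold. The checkpoint kinase gene BUB1B was at 240.1 CPM against 69.2 CPM, and MAD1L1, of the same checkpoint, at 10.5 CPM against 150.2 CPM. Cyclin B1, CCNB1, was at 2633 CPM (2282 to 2999.6) against 1226 CPM (809.7 to 1458). MOS, the kinase upstream of metaphase II arrest, was at 1759 CPM (631 to 2956) against 2047 CPM (1422 to 4283), and its log2 difference of -0.22 turned to 0.11 with trimmed-mean (TMM-like) factors and to 0.07 without GV replicate 9. The spindle list lay at percentile 97.46 and the cell cycle list at 95.1, both within the central 95% of random lists.

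Of 33 oocyte-specific and maternal-effect genes, 10 were at least 2-fold higher, 9 at least 2-fold lower and 14 under 2-fold. The transcription factor gene FIGLA was at 33.7 CPM (20.3 to 60.4) against 752 CPM (397 to 1273), and the zona pellucida gene ZP3 at 644 CPM (246 to 1249) against 3058 CPM (1530.3 to 8420.4). The growth factor gene BMP15 was at 2250.3 CPM (1320.3 to 3360.3) against 764 CPM (542 to 1085), and the deadenylation adaptor gene BTG4 at 19952 CPM (11543 to 28829) against 9807 CPM (5675 to 12339). ACCSL was at 10576 CPM (5206 to 15178) against 3116 CPM (2359 to 5178). GDF9 was at 695 CPM (511 to 937) against 820.3 CPM (514 to 1045), a log2 difference of -0.24 that turned to 0.10 with TMM-like factors. The list's median of -0.23 lay at percentile 0.98 among lists of like expression, and it turned to 0.10 with TMM-like factors.

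CNP signals through the receptor NPR2 and cyclic GMP, which inhibits the cyclic AMP phosphodiesterase PDE3A in the oocyte. The table held no row for NPPC, the CNP gene. NPR2 averaged 0.361 CPM (0 to 1.18) after IVM and 2.39 CPM (0.0545 to 5.94) in GV oocytes. PDE3A was at 38.6 CPM (20.5 to 62.9) against 8.40 CPM (0.0272 to 13.8), and the cyclic GMP phosphodiesterase gene PDE5A at 82.02 CPM (56.3 to 106) against 25.2 CPM (1.17 to 35.3). GPR3, the receptor that keeps cyclic AMP high in the oocyte, was at 10.2 CPM (2.48 to 21.6) against 6.60 CPM (2.59 to 18.1). AKAP11, an anchor of protein kinase A, was at 214 CPM (118 to 279) against 41.2 CPM (5.18 to 58.99). Of 43 cyclic nucleotide genes, 9 were at least 2-fold higher, 6 at least 2-fold lower and 28 under 2-fold, and the list lay at percentile 96.6.

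Follicle and blood cell markers were lower in sum after IVM, beside the gene groups above. The marker STAR, at 547 to 844 CPM in GV and 175 to 452 CPM after IVM, carried much of the follicle-cell difference. Of 19 cumulus and granulosa markers, 2 were at least 2-fold higher, 9 at least 2-fold lower and 8 under 2-fold, at percentile 26.1. HAS2, the hyaluronan synthase of cumulus expansion, was at 77.1 CPM (61.1 to 94.8) against 16.3 CPM (9.78 to 25.97). HSD3B1, a granulosa marker, stayed below the filter on low values. It averaged 0.354 CPM (0 to 0.810) after IVM and 3.71 CPM (0.0327 to 23.8) in GV. The highest GV value was that of replicate 9. Of 4 blood and immune markers, 3 were at least 2-fold lower, with VWF at 21.1 CPM (1.92 to 42.1) against 225 CPM (159.9 to 336) and CD3E at 3.55 CPM (0.347 to 5.91) against 29.4 CPM (10.5 to 64.7). The 4-gene list lay at percentile 2.30, and at 2.55 and 3.05 with quantile normalization and TMM-like factors.

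Over all 11852 genes past the filter, 1880 were at least 2-fold higher and 3917 at least 2-fold lower after IVM than in GV oocytes, which puts 32.4% of them on the higher side. The median log2 difference of all genes was -0.28. Quantile normalization moved the median to 0.15 and gave 3119 higher and 2836 lower (52.4% higher), and TMM-like factors moved it to -0.0031 and gave 2838 higher and 3270 lower (46.5% higher). Relative to the median of all genes as reported, ribosomal protein genes stood at -1.74, nuclear respiratory genes at -1.90, DNA repair genes at 1.27 and chromatin genes at 0.97. Summed over the oocytes of a group, GPX4 was at 14.9 CPM (14.5 to 15.4) after IVM and 961 CPM (957 to 966) in GV, with 95% exact Poisson intervals in parentheses. Such intervals cover the counting of reads only, not that of captured RNA molecules or the spread between oocytes.

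**Figure D1:**
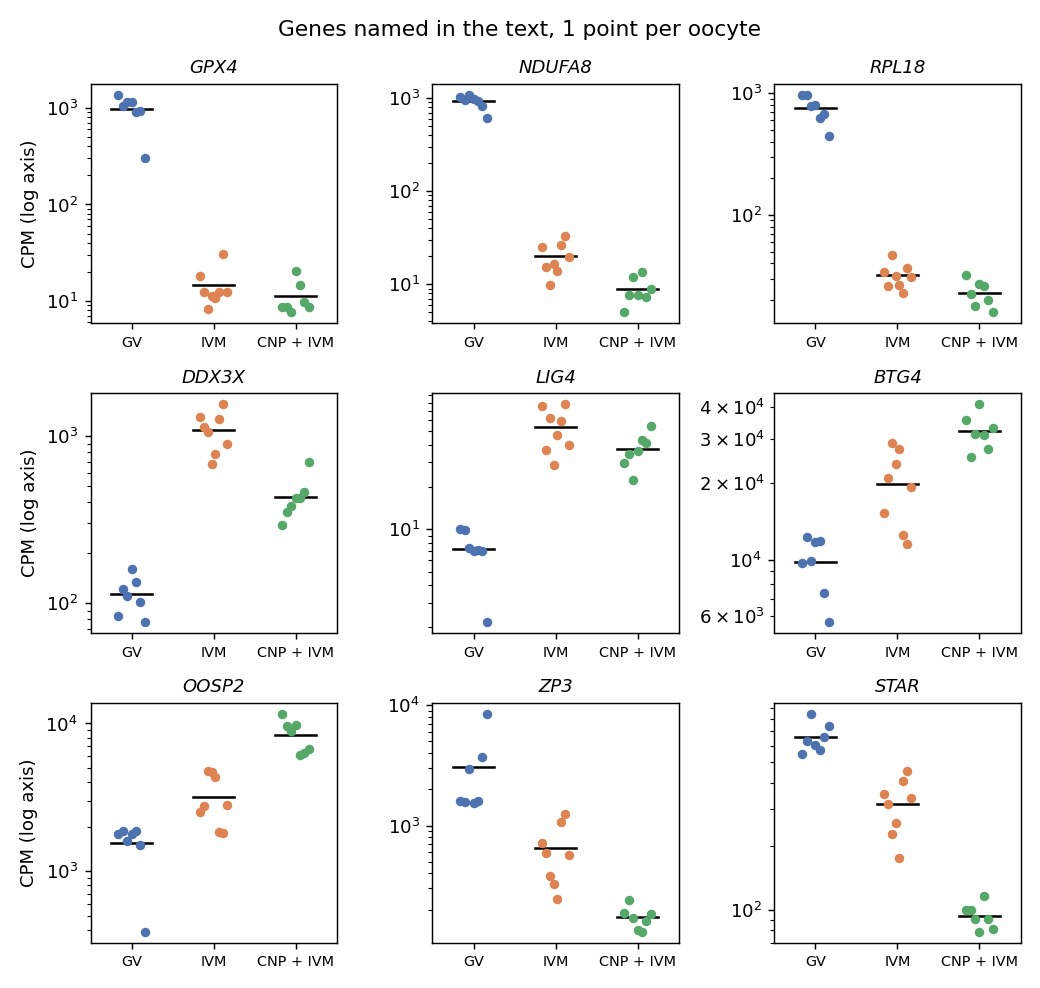
Levels in CPM on a log axis of 9 genes, with 1 point per oocyte for 7 GV, 8 IVM and 7 CNP_IVM oocytes and a line at each group mean. GPX4, NDUFA8, RPL18 and ZP3 are lower in both matured groups than in GV, DDX3X and LIG4 are higher, and ZP3 and STAR are lower after CNP_IVM than after IVM. BTG4 is higher after CNP_IVM than after IVM by 0.68 on the log2 scale, a direction that turns to -0.09 with quantile normalization.

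The second comparison sets CNP_IVM against the same GV oocytes. The medians of the translation, respiration, glycolysis, proteasome and antioxidant lists lay low here too, and transcripts of the mitochondrial genome were higher. ATP6, a mitochondrial subunit of ATP synthase, was at 1883 CPM (982 to 3999) after CNP_IVM against 259.6 CPM (182 to 389) in GV oocytes, a log2 difference of 2.85. ND4, of respiratory complex I, was at 1128 CPM (576 to 2105) against 179 CPM (126 to 278). AZIN1, a regulator of polyamine synthesis, was at 106 CPM (76.1 to 125) against 15.2 CPM (0.163 to 19.5), and HAS2 at 118 CPM (98.3 to 149.6) against 16.3 CPM (9.78 to 25.97). In the other direction, GPX4 was at 11.2 CPM (7.62 to 20.3) and NDUFA8 at 8.88 CPM (4.99 to 13.7), log2 differences of -6.34 and -6.54 from the GV means above. ACAA1, of peroxisomal fatty acid oxidation, was at 1.19 CPM (0.153 to 3.96) against 158 CPM (113 to 213).

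All 13 genes of the mitochondrial genome were at least 2-fold higher after CNP_IVM than in GV, with a median log2 difference of 2.56, above all 10000 random lists. Their summed level was 16944 ± 7124 CPM (7908 to 30207) against 3189.7 ± 1067 CPM (2277 to 4834). After IVM none of the 13 was 2-fold away from GV, with a median of 0.41 at percentile 38.5. By contrast, of the nuclear respiratory genes 5 were at least 2-fold higher, 62 at least 2-fold lower and 15 under 2-fold, with a median of -2.52. Of the mitochondrial ribosomal genes 1 was at least 2-fold higher, 58 at least 2-fold lower and 17 under 2-fold, with MRPL28 at 0.397 CPM against 87.7 CPM. Of the cytosolic ribosomal genes 2 were at least 2-fold higher, 60 at least 2-fold lower and 19 under 2-fold, with RPL26L1 at 838 CPM against 382 CPM. Translation factors had 13 members at least 2-fold higher and 34 lower, with EIF4A2 at 545 CPM (432 to 649) against 143 CPM (17.1 to 206). Glycolysis and citric acid cycle genes had 7 higher and 30 lower, proteasome genes 5 and 28, and antioxidant genes 5 and 25. These lists lay below the 2.5th percentile of random lists, at 0.020 for translation factors, 0.18 for glycolysis, 0.13 for the proteasome and 0.63 for the antioxidant list, which stood at 3.85 without GV replicate 9 and at 3.80 with quantile normalization.

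Of the DNA repair genes, 21 were at least 2-fold higher, 12 at least 2-fold lower and 16 under 2-fold, with a median of 0.89 at percentile 99.97. PCNA, the sliding clamp of DNA polymerases, was at 3071 CPM (2601 to 3524) against 772 CPM (57.1 to 978). Of the messenger RNA decay genes, 20 were at least 2-fold higher, 15 at least 2-fold lower and 32 under 2-fold, with a median of 0.59 at percentile 99.99. The deadenylase gene CNOT6L was at 262 CPM (179 to 348) against 40.01 CPM (18.7 to 50.2), and PAN3, of another deadenylase complex, at 96.5 CPM (68.96 to 135) against 18.4 CPM (11.4 to 26.9). Of the chromatin genes, 17 were at least 2-fold higher, 11 at least 2-fold lower and 31 under 2-fold, with DNMT1, the maintenance DNA methyltransferase, at 802 CPM (704 to 890.1) against 189 CPM (37.3 to 242) and the acetyltransferase gene EP300 at 47.4 CPM (28.6 to 58.6) against 12.4 CPM (7.46 to 19.1). The chromatin list lay at percentile 99.4, and at 96.5 with quantile normalization and 96.8 without GV replicate 9. Of the spindle genes, 18 were at least 2-fold higher, 12 at least 2-fold lower and 12 under 2-fold, with the alpha-tubulin gene TUBA1B at 40.7 CPM (30.2 to 55.8) against 1272 CPM (900.0 to 1492). Of the cell cycle genes, 12 were at least 2-fold higher, 13 at least 2-fold lower and 26 under 2-fold, with the securin gene PTTG1 at 31069 CPM (27601 to 37674) against 8081 CPM (1301 to 11580.4). Spindle and cell cycle lists lay at percentiles 86.5 and 66.1.

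Of the oocyte factors, 5 were at least 2-fold higher, 15 at least 2-fold lower and 13 under 2-fold, with a median of -0.47 at percentile 1.32. OOSP2, a secreted oocyte protein, was at 8400.0 CPM (6072 to 11555) against 1538 CPM (387 to 1867), and BTG4 at 32075 CPM (25421 to 40963), a log2 difference of 1.71. ZP3 was at 172 CPM (130.3 to 239), GDF9 at 378 CPM (315 to 447) and MOS at 864 CPM (523 to 1627), with log2 differences of -4.14, -1.12 and -1.24 from GV. GDF9 and MOS stood at -0.45 and -0.55 with TMM-like factors, and at -1.25 and -1.54 with quantile normalization. MOS was at -0.95 without GV replicate 9. Of the histone genes, 1 was at least 2-fold higher, 20 at least 2-fold lower and 14 under 2-fold, at percentile 7.72, and H3-3A, which codes for a replication-independent histone H3, was at 2499 CPM (2207 to 2904) against 668 CPM (476 to 765). Of the cyclic nucleotide genes, 9 were at least 2-fold higher, 12 at least 2-fold lower and 22 under 2-fold, and the median of -0.30 turned to 0.57 with quantile normalization and 0.10 with TMM-like factors. PDE3A was at 25.9 CPM (14.1 to 30.9), PDE5A at 63.5 CPM (40.7 to 86.5) and GPR3 at 2.26 CPM (0.0793 to 4.82). NPR2 was at 0.905 CPM (0.103 to 1.63), and its log2 difference of -0.83 from GV turned to 0.12 with quantile normalization. Beside these groups, 10 of 19 cumulus and granulosa markers were at least 2-fold lower, with the secreted chaperone gene CLU at 4.02 CPM (1.52 to 6.52) against 107 CPM (52.2 to 149), and 3 of 4 blood and immune markers.

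Over all genes, 1818 were at least 2-fold higher and 4977 at least 2-fold lower after CNP_IVM than in GV (26.8% higher), with a median log2 difference of -0.61. Quantile normalization gave 3541 higher and 3123 lower (53.1% higher) with a median of 0.15, and TMM-like factors 3253 higher and 3762 lower (46.4% higher) with a median of -0.063. Relative to the median of all genes as reported, the mitochondrial genome stood at 3.17, DNA repair genes at 1.50 and nuclear respiratory genes at -1.91. Both comparisons share the 7 GV oocytes, so their differences are not independent.

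**Figure D2:**
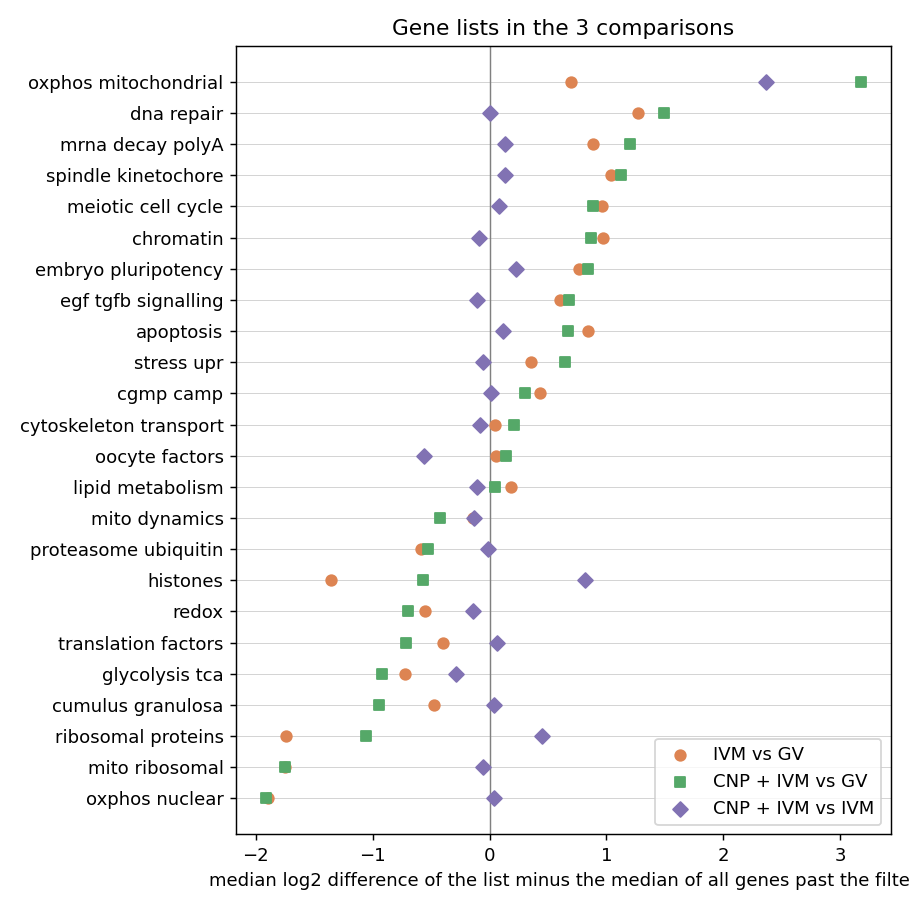
Median log2 difference of each gene list minus the median of all genes past the filter (horizontal axis, log2 units), for 24 lists of at least 5 genes (vertical axis) and 3 comparisons (symbols). Nuclear respiratory genes stand at -1.90 and -1.91 against GV, and the mitochondrial genome at 2.37 in CNP_IVM against IVM.

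The third comparison sets the MII oocytes of both culture systems against each other, and addresses the question of the series, whether pre-maturation with CNP goes with a different transcriptome. Transcripts of the mitochondrial genome were higher after CNP_IVM than after IVM, and many oocyte factors and the steroidogenic marker STAR were lower. ND3 was at 247 CPM (89.3 to 647) after CNP_IVM against 37.7 CPM (14.8 to 84.9) after IVM, a log2 difference of 2.68. ATP6 was at 1883 CPM (982 to 3999) against 317 CPM (147 to 830.3), ND2 at 446 CPM (330.0 to 651) against 89.7 CPM (43.2 to 193) and ND4 at 1128 CPM (576 to 2105) against 239 CPM (127 to 562). RNF166, a ubiquitin ligase gene, was at 3.21 CPM (2.08 to 4.96) against 50.5 CPM (12.5 to 107), a log2 difference of -3.61. For these 5 genes every CNP_IVM oocyte lay on one side of every IVM oocyte, as it did for ND1 and ND6. The other mitochondrial genes (COX2, COX3, ATP8, ND4L, CYTB, ND5 and COX1) overlapped. For all of these but COX1, IVM replicate 3 was the only IVM oocyte to reach the CNP_IVM range. For COX1, the lowest CNP_IVM oocyte was at 1072 CPM, and IVM replicates 3 and 6 were at 2010 and 1075 CPM.

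All 13 mitochondrial genes were at least 2-fold higher, with a median log2 difference of 2.08, 2.09 with quantile normalization and 2.40 with TMM-like factors, above all 10000 random lists. Their sum was 16944 ± 7124 CPM (7908 to 30207) after CNP_IVM and 4131 ± 2275 CPM (2205 to 9414) after IVM, a ratio of 4.10. IVM replicate 3 had the highest IVM sum, and the ratio was 5.02 without it. Overlapping mitochondrial genes, nuclear copies of them and ND6, which lies on the opposite strand and whose counting was not stated to use strand, are uncertain singly. Nuclear respiratory genes did not stand apart: 4 were at least 2-fold higher, 15 at least 2-fold lower and 63 under 2-fold, with UQCRH, of respiratory complex III, at 665 CPM (531 to 941) against 286 CPM (156 to 383). Their median of -0.25 turned to 0.04 with quantile normalization and 0.03 with TMM-like factors. Of the mitochondrial ribosomal genes 0 were at least 2-fold higher, 13 at least 2-fold lower and 63 under 2-fold, with MRPL37 at 36.01 CPM (23.5 to 43.8) against 179 CPM (67.3 to 373), at percentile 15.6.

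**Figure D3:**
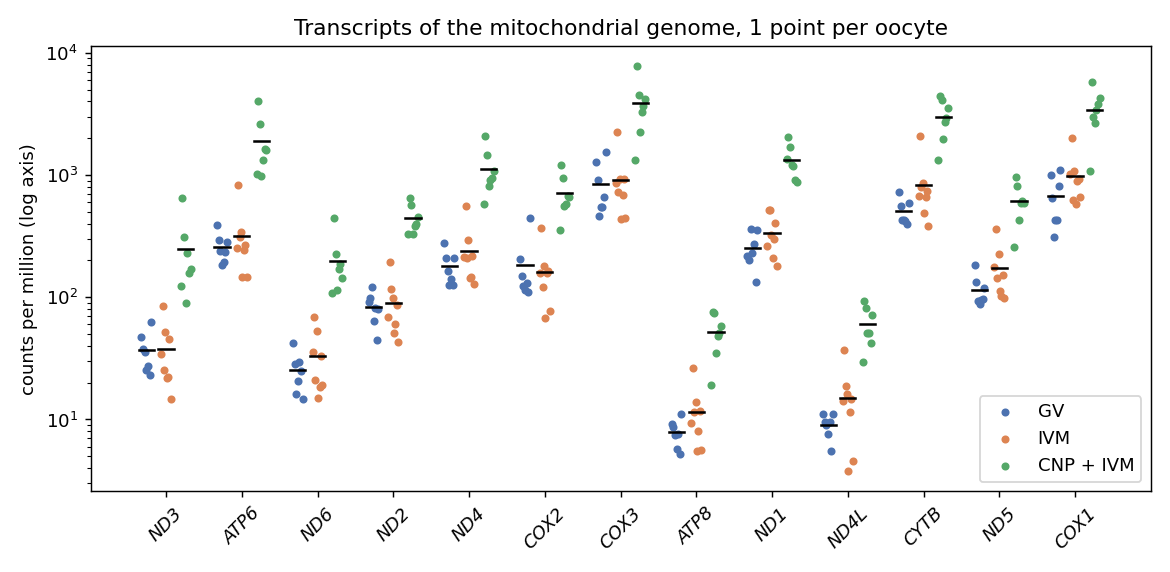
Levels in CPM on a log axis of the 13 protein-coding genes of the mitochondrial genome, with 1 point per oocyte and a line at each group mean for 7 GV, 8 IVM and 7 CNP_IVM oocytes. Each gene's CNP_IVM mean is at least 2-fold above its IVM mean, also with quantile normalization and TMM-like factors.

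Of the 33 oocyte factors, 1 was at least 2-fold higher, 12 at least 2-fold lower and 20 under 2-fold in CNP_IVM against IVM. The median log2 difference was -0.85, -0.78 with quantile normalization and -0.49 with TMM-like factors, below all 10000 random lists. PADI6, of the subcortical maternal complex, was at 19.4 CPM (12.995 to 31.04) against 159 CPM (26.98 to 345), and ASTL, the zona-cleaving protease ovastacin, at 29.1 CPM (19.8 to 40.1) against 136 CPM (34.5 to 329.9). ZP3 was at 172 CPM (130.3 to 239) against 644 CPM (246 to 1249) and GDF9 at 378 CPM (315 to 447) against 695 CPM (511 to 937). BMP15 was at 1219 CPM (907 to 1567) against 2250.3 CPM (1320.3 to 3360.3) and MOS at 864 CPM (523 to 1627) against 1759 CPM (631 to 2956). OOSP2 was the member at least 2-fold higher, at 8400.0 CPM (6072 to 11555) against 3197 CPM (1819.9 to 4749). BTG4 was at 32075 CPM (25421 to 40963) against 19952 CPM (11543 to 28829), a log2 difference of 0.68 that turned to -0.09 with quantile normalization. The list's summed level, which a few abundant members carry, was 68566 ± 6309.7 CPM (63211 to 78605) against 63788 ± 4451 CPM (58018 to 68292).

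The medians of histone and ribosomal protein genes were higher after CNP_IVM than after IVM, while most members were under 2-fold. Of 35 histone genes, 6 were at least 2-fold higher, 1 at least 2-fold lower and 28 under 2-fold, with a median of 0.53, 0.84 with quantile normalization and 0.67 with TMM-like factors. H2BC18 was at 128 CPM (74.7 to 184) against 46.3 CPM (40.2 to 58.3) and H3-3A at 2499 CPM (2207 to 2904) against 1244 CPM (792 to 1713), while SLBP was at 338 CPM (209 to 519) against 714 CPM (486 to 1135). The summed level of the histone list went the other way by little, at 7199 ± 476 CPM (6582 to 7823) against 7341 ± 567 CPM (6351 to 8146), a ratio of 0.981. Of 81 cytosolic ribosomal protein genes, 3 were at least 2-fold higher, 1 at least 2-fold lower and 77 under 2-fold, with a median of 0.17, 0.44 with quantile normalization and 0.49 with TMM-like factors. RPS28 was at 110.3 CPM (72.8 to 185) against 47.2 CPM (36.99 to 54.2) and RPL39 at 57.03 CPM (37.2 to 88.5) against 26.2 CPM (14.9 to 31.5), and the list summed to 8547 ± 1441 CPM (6933 to 11381) against 7133 ± 915 CPM (5276 to 8131). The medians of both lists lay above all 10000 random lists. Of 46 glycolysis and citric acid cycle genes, 0 were at least 2-fold higher, 11 at least 2-fold lower and 35 under 2-fold, with a median of -0.57 at percentile 0.71. The glycolytic enzyme gene GPI was at 33.3 CPM (22.4 to 55.1) against 114 CPM (45.3 to 180.1) and GAPDH at 83.4 CPM (55.7 to 111) against 232 CPM (96.7 to 451).

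Of 19 cumulus and granulosa markers, 0 were at least 2-fold higher, 4 at least 2-fold lower and 15 under 2-fold, and the list's median of -0.25 turned to 0.15 with quantile normalization and 0.03 with TMM-like factors. The protease inhibitor gene SERPINE2 was at 10.7 CPM (4.76 to 15.5) against 55 CPM (34.4 to 81.99), and STAR, which carries cholesterol into mitochondria, at 93.9 CPM (78.6 to 117) against 316 CPM (175 to 452). Of 43 cyclic nucleotide genes, 0 were at least 2-fold higher, 6 at least 2-fold lower and 37 under 2-fold, and the median of -0.27 turned to 0.17 and 0.04 under the same scalings. GPR3 was at 2.26 CPM (0.0793 to 4.82) against 10.2 CPM (2.48 to 21.6), and PDE6D at 116 CPM (87.2 to 139.9) against 240.2 CPM (152 to 291). PDE3A, PDE5A and NPR2 had log2 differences of -0.56, -0.36 and 0.49, with oocytes of both groups overlapping. Of 67 messenger RNA decay genes, 3 were at least 2-fold higher, 11 at least 2-fold lower and 53 under 2-fold, with the poly(A)-binding protein gene PABPC1 at 251 CPM (123 to 353) against 91.3 CPM (48.6 to 189). The decay list's median of -0.15 turned to 0.02 with quantile normalization and 0.17 with TMM-like factors. CCNB1 had a log2 difference of -0.26 that turned to 0.04 with TMM-like factors, and the cyclin gene CCNB3 was at 199 CPM (132 to 279) against 562 CPM (354 to 872).

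Over all genes, 220 were at least 2-fold higher and 1754 at least 2-fold lower after CNP_IVM than after IVM (11.1% higher), with a median log2 difference of -0.28. Quantile normalization gave 462 higher and 663 lower (41.1% higher) with a median of 0.017, and TMM-like factors 501 higher and 894 lower (35.9% higher) with a median of -0.022. Relative to the median of all genes as reported, the mitochondrial genome stood at 2.37, histones at 0.82, ribosomal proteins at 0.45 and oocyte factors at -0.56. Of the 1754 genes lower after CNP_IVM than after IVM, 763 were also at least 2-fold lower after IVM than in GV, 191 were higher and 800 were under 2-fold. Of the 220 higher genes, 11 were also higher after IVM than in GV, 39 were lower and 170 were under 2-fold. Both tallies share the IVM oocytes, which pushes them toward opposite directions. Summed over oocytes, ND3 was at 248 CPM (246 to 249.8) after CNP_IVM and 37.6 CPM (36.9 to 38.4) after IVM, with 95% exact Poisson intervals for the counting of reads in parentheses.

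A maturation score placed each oocyte between GV and MII, as the mean log2 level of 1858 genes that were at least 2-fold higher in the matured groups minus that of 4323 genes that were at least 2-fold lower. It was 3.34 ± 0.32 (SD, n = 8) after IVM, with oocytes from 3.0 to 3.77, and 3.84 ± 0.13 (SD, n = 7) after CNP_IVM, from 3.66 to 4.01. IVM replicates 5, 6 and 7 scored 3.77, 3.65 and 3.72, at or near the CNP_IVM range, and the other IVM oocytes at most 3.28. Those replicates also had the fewest genes at 1 CPM or more in IVM (9460, 9817 and 9431). Their ZP3 (378, 328 and 246 CPM) and STAR (229, 259 and 175 CPM) were the lowest in IVM. The IVM means thus cover oocytes that were unlike each other. The genes were chosen from these libraries, so the gap between GV and matured oocytes was built in. Distance of an oocyte to the mean of the others in its group, as 1 minus Spearman's rho over genes, was 0.0374 ± 0.0135 (SD, n = 8) after IVM and 0.0345 ± 0.00524 (SD, n = 7) after CNP_IVM. The difference of -0.00295 was smaller than either SD and turned to 0.000587 without IVM replicate 8. It was -0.00764 with Pearson correlation and -0.0116 with a filter of 5 CPM in at least 6 libraries.

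**Figure D4:**
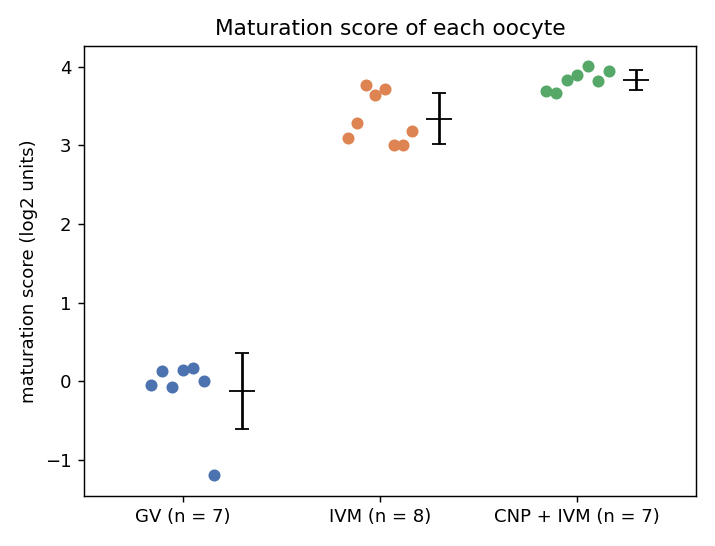
Maturation score in log2 units of each oocyte (points) with the group mean and SD (bars) for 7 GV, 8 IVM and 7 CNP_IVM oocytes. IVM oocytes lie between 3.0 and 3.77, CNP_IVM oocytes between 3.66 and 4.01, and GV replicate 9 lies at -1.19 below the other GV oocytes.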

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

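The tests of a mislabelled oocyte, of follicle-cell RNA, of capture and of scaling were chosen only after the results they address had been seen, and the bounds for follicle-cell markers and for abundant transcripts after those values were known. A value is given here when its gap to the nearest of the other oocytes of its group, divided by the group's range, exceeds Dixon's 95% critical value for the number of oocytes in the group. Gap and range were taken on log2 of CPM plus 1 for genes, whose values are printed in CPM, and without a log for library measures. For unselected values chance gives about 1 in 20 groups, or 15.3 of the 306 groups of oocytes formed by 102 named genes. These genes were picked partly for values that did not rest on 1 oocyte, so that number is not their chance rate. There were 46, of which 39 fell on GV replicate 9. Of 33 groups of library measures there were 5.

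GV replicate 9 stood apart from the other GV oocytes. It had 9381 genes at 1 CPM or more against 11311 to 11798 in the others, a maturation score of -1.19 against -0.076 to 0.17, and a distance of 0.213 to its group against 0.0253 to 0.0337. Its treatment label names in vitro maturation, but with genes chosen without the oocyte scored its score was -0.49, below the other GV oocytes (-0.026 to 0.23) and the lowest IVM oocyte (2.95), which argues against a matured oocyte under a GV title. Its summed oocyte factors were 1.03 times the mean of the others while 705 genes of over 5 CPM in the others were at 0 in it (at most 4 in any other GV oocyte), which argues against dilution by follicle-cell RNA as the source of the missing transcripts. The percent of genes at 0 was 24.98% at 5 to 10 CPM and 0.0479% at 100 CPM or more, a ratio of 0.00192. Most kinds of loss, though, leave fewer zeros among abundant genes. Random draws in proportion to level, set to the first percent, would give 6.59% at 10 to 20 CPM, 0.246% at 20 to 50 and 1.5e-04% at 50 to 100. The percents seen were 12.5%, 3.94% and 1.07%, which argues against such draws as the only source from 20 CPM up. Whether fewer captured molecules account for part of the missing transcripts cannot be told apart from another loss of transcripts. Capture alone is argued against for the abundant transcripts that were lower, since 17.2% of genes at 1000 CPM or more, and 16.8% at 100 to 1000 CPM, lay over 2-fold below the lowest other GV oocyte (0% and at most 0.2996% in any other GV oocyte). For the transcripts that were higher in it, follicle-cell RNA cannot be told apart from other sources: of 24 follicle-cell genes of a separate list, 45.8% were highest in it, against 33.3% of other genes, at percentile 90.1 of random lists, though CDH2 (57.0 CPM against at most 1.50 in another GV oocyte), IGFBP7 (47.4 against 3.50) and GSTA1 (122 against 15.3) were far above the others, and its summed cumulus and granulosa markers were the highest (1515 CPM, then 1149 CPM), while TMSB4X was lower (4461 CPM against at least 6116 CPM). The granulosa marker HSD3B1, which did not pass the filter, was also highest in it, at 23.8 CPM. No biological explanation was tested.

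Of the named genes, GV replicate 9 was lowest for GPX4 (306 CPM), POLR2G (297), PSMB5 (230.2), H2AC6 (7.52), LIG4 (2.18), HDAC1 (0.2997), XRN1 (13.1), SMC3 (30.2), BUB1B (8.37), PDE3A (0.0272), PDE5A (1.17), AKAP11 (5.18), AZIN1 (0.163), CNOT6L (18.7), OOSP2 (387), H3-3A (476), TUBA1B (900.0), DNMT1 (37.3), PCNA (57.1), PTTG1 (1301), MRPL28 (18.1), RPL26L1 (230.3), EIF4A2 (17.1), H2BC18 (104), BIRC6 (14.5), OPA1 (20.8), DNAJB1 (65.9) and CCNB3 (149). It was highest for MOS (4283 CPM), PADI6 (862), RPS28 (149), RPL39 (193), GPI (690.2), PDE6D (835), SMAD2 (335), ELOVL1 (281), PPARG (288), PDIA3 (104) and BNIP3 (256).

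Summed transcripts of the mitochondrial genome were highest in IVM replicate 3, at 9414 CPM against 2205 to 4456 CPM in the other IVM oocytes. The pattern beside it, higher mitochondrial-genome transcripts after CNP_IVM than after IVM, was weighed too. Scaling between libraries is argued against, since 13 of the 13 genes stayed at least 2-fold higher under both quantile normalization and TMM-like factors. For RNA of attached follicle cells, 19 markers were set against the rise of the summed mitochondrial transcripts. That rise was 4.10 times as reported, 3.98 with quantile normalization and 5.08 with TMM-like factors. At most 1 marker reached it: FST, at about 1 CPM, at 4.13 times with quantile normalization. This bound cannot exclude such RNA, since a marker that the oocyte itself holds would rise by less. The median marker was 0.791 times as high, 1.13 with quantile normalization and 1.02 with TMM-like factors, though HAS2 was higher in every CNP_IVM oocyte (98.3 to 149.6 CPM) than in any IVM oocyte (61.1 to 94.8 CPM). CNP and the longer culture cannot be told apart, because every CNP_IVM oocyte spent 28 h in culture, and a difference in poly(A) tails of mitochondrial transcripts, which sets their capture, was not tested and may contribute.

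The other values outside their group were single ones. The 50 most abundant genes took 20.7% of reads in GV replicate 2 against 16.7 to 18.1% in the other GV oocytes. Among IVM oocytes, CD3E was lowest in replicate 7 (0.347 CPM), AZIN1 lowest in replicate 9 (57.7 CPM), DNMT1 highest in replicate 5 (843 CPM), RPL39 lowest in replicate 8 (14.9 CPM) and BID lowest in replicate 6 (0.756 CPM). Among CNP_IVM oocytes, PDE3A was lowest in replicate 1 (14.1 CPM) and SMAD2 lowest in replicate 2 (61.4 CPM).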

How the results depend on the processing

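The mean of log2 values, reads summed over oocytes, list percentiles under other settings and the number of genes per oocyte without GV replicate 9 were chosen only after the results had been seen. Normalization between libraries and the pseudocount both moved the counts. With quantile normalization, genes at least 2-fold higher numbered 3119 in IVM against GV and 3541 in CNP_IVM against GV, where 3123 were lower, and CNP_IVM against IVM gave 462 higher and 663 lower. With TMM-like factors, 2838, 3253 and 501 genes were higher in the same order of comparisons, and 894 were lower in the last. With a pseudocount of 0.1 CPM, CNP_IVM against IVM gave 395 higher and 2793 lower, and with 5 CPM 113 and 743. The construction of these settings shows part of the cause, since a small pseudocount widens and a large one narrows the differences of low genes, and the other causes were not tested. The other 41 recomputed counts stayed within 1.5 times the reported ones. Leaving out 1 library at a time gave 1813 to 1979 higher and 3761 to 4102 lower genes in IVM against GV, 1763 to 1861 and 4796 to 5036 in CNP_IVM against GV, and 170 to 260 and 1389 to 2060 in CNP_IVM against IVM.

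The median of the oocyte factor list in IVM against GV turned to 0.10 with TMM-like factors, and the cause was not tested. It was 1 of 15 medians, of 75 in the 3 comparisons, whose sign changed with TMM-like factors, and 11 changed with quantile normalization, but the only one of a list outside the central 95% of random lists. Of all other list medians, whatever their sign, 533 stayed within 1 SD between oocytes of the reported value and 114 moved further. Without 1 library, 1646 stayed and 4 moved further: stress genes in IVM against GV (0.40 without GV replicate 9) and in CNP_IVM against GV (-0.35 without CNP_IVM replicate 2), and antioxidant genes against GV (-0.52 after IVM and -0.93 after CNP_IVM, without GV replicate 9). Of recomputed values of single genes taken by the rule, 2697 stayed within 1 SD and 207 moved further, and without 1 library 7170 and 2.

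The difference in genes per oocyte between CNP_IVM and GV was -1667 at 1 CPM, -1761 at 5 CPM, -1025 at 0.1 CPM and -1990 at 1 CPM without GV replicate 9, and the cause of the smaller value was not tested. The maturation score difference between CNP_IVM and IVM of 0.50 lay between 0.39 and 0.70 under other gene choices, pseudocounts and quantile normalization, and between 0.45 and 0.54 without 1 library. The spread difference of -0.00295 lay between -0.0116 and -0.00764 under another correlation or filter, and between -0.00707 and 0.000587 without 1 library, the positive value being that without IVM replicate 8.

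No paired analysis was possible because the labels name no donor or culture that would link oocytes across groups. Choices made before the data were examined that only change a test (variance models, weights, thresholds on p-values, rank tests, a covariate for genes detected, an estimated correlation, another list test and the overlap of calls) are not given, because the results come from no test and each group counts as 1 sample. Read depth limits little: 3 reads correspond to 0.0763 to 0.149 CPM. The number of RNA molecules captured per oocyte is not known.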

Other observations

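Gene lists not described above were read in the same way. Their percentiles among random lists, like those above, were chosen only after the results had been seen, and the lists themselves were not. Of 22 apoptosis genes, 6 were at least 2-fold higher, 6 at least 2-fold lower and 10 under 2-fold after IVM than in GV, at percentile 99.2 (93.9 without GV replicate 9). BIRC6, an inhibitor of apoptosis, was at 108 CPM (92.7 to 136) against 28.6 CPM (14.5 to 37.04), APAF1, the scaffold of the apoptosome, at 166 CPM (139 to 232) against 50.99 CPM (36.4 to 67.7), and BID, which promotes apoptosis, at 6.46 CPM (0.756 to 12.8) against 73.4 CPM (51.5 to 110.1). Of 45 stress and unfolded protein genes, 10 were at least 2-fold higher, 10 at least 2-fold lower and 25 under 2-fold, with the disulfide isomerase gene PDIA3 at 197 CPM (106 to 312) against 50.7 CPM (35.4 to 104) and the co-chaperone gene DNAJB1 at 20.8 CPM (10.6 to 48.3) against 111 CPM (65.9 to 136). HSP90B1, a chaperone of the endoplasmic reticulum, was at 864 CPM (657 to 1246) after CNP_IVM against 228 CPM (136 to 295) in GV. Of 34 mitochondrial dynamics genes, 5 were at least 2-fold higher, 14 at least 2-fold lower and 15 under 2-fold, with OPA1, of inner membrane fusion, at 460.2 CPM (358 to 619.9) against 127 CPM (20.8 to 170.1) and the importer gene TIMM23 at 35.5 CPM (17.4 to 64.2) against 512 CPM (399.6 to 576). In CNP_IVM against IVM, 4 of them were at least 2-fold lower, among them the mitophagy receptor gene BNIP3 (40.2 CPM (20.6 to 74.9) against 143 CPM (59.2 to 240.0)). Stress and dynamics lists lay within the central 95% of random lists, at percentiles 52.4 and 13.8 in IVM against GV and 24.6 and 8.68 in CNP_IVM against IVM.

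Of 63 lipid metabolism genes, 15 were at least 2-fold higher, 22 at least 2-fold lower and 26 under 2-fold after IVM than in GV, and the median of -0.10 turned to 0.29 with quantile normalization and 0.16 with TMM-like factors. The elongase gene ELOVL1 was at 14.4 CPM (6.45 to 22.9) against 172 CPM (133 to 281). In CNP_IVM against IVM, 14 were at least 2-fold lower and 0 higher, with the lipid-sensing receptor gene PPARG at 57.1 CPM (46.4 to 74.6) against 129.8 CPM (93.8 to 154), at percentile 12.6. Of the antioxidant genes, 1 was at least 2-fold higher and 9 were lower in the same comparison, with SOD2, the mitochondrial superoxide dismutase, at 32.8 CPM (14.6 to 49.1) against 93.6 CPM (45.6 to 135). Of 43 cytoskeleton and transport genes, 7 were at least 2-fold higher, 11 at least 2-fold lower and 25 under 2-fold after IVM than in GV, with ARPC4, of the Arp2/3 complex, at 10.7 CPM (4.83 to 25.6) against 196 CPM (150.1 to 245), and the median of -0.24 turned to 0.16 and 0.09 under the same scalings. Of 41 EGF, TGF-beta and PI3K signalling genes, 12 were at least 2-fold higher, 5 at least 2-fold lower and 24 under 2-fold, with RICTOR, of the mTORC2 complex, at 73.7 CPM (39.2 to 101) against 17.1 CPM (9.46 to 23.8) and the p38 kinase gene MAPK14 at 40.2 CPM (18.3 to 97.3) against 206 CPM (154 to 291). SMAD2, a mediator of TGF-beta signals, was at 117 CPM (61.4 to 143) after CNP_IVM against 279.9 CPM (242 to 340.4) after IVM. Of 10 embryonic genome activation and pluripotency genes, 2 were at least 2-fold higher, 0 at least 2-fold lower and 8 under 2-fold, with HNRNPK at 80.3 CPM (38.2 to 117) against 31.8 CPM (18.9 to 38.1).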
